A study of Mus musculus with 8 samples.

How the data were processed

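Poly(A)-selected RNA of mouse APS colon cancer organoids was sequenced in 8 libraries, 2 for each combination of 2 organoid lines (apsMC706 and CTO19) and 2 media (with EGF for 3 days, EM, and without EGF for 7 days, noEGF). Per the labels, total RNA was extracted with a column kit, and libraries were made with a poly(A) isolation module and a kit whose protocol does not mark the strand, with 8 cycles of amplification. The authors aligned reads with STAR 2.7.0a to the mm10 build. The counting program, its strand setting, the annotation release and any filter on genes are not given in the sources used here. The deposited table holds raw counts per Ensembl gene, and its values were whole numbers in every library. Of 32728 genes in the table, 32680 were found by identifier in the GENCODE M21 annotation, 48 were not, and 7747 had no count in any library. Names, positions and overlaps with other genes were taken from that annotation.

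Library totals ranged from 35650262 to 38953838 counts. A count of 0 allows up to 3 counts per library, which was 0.0745 to 0.0868 CPM. Floors and intervals cover counting error only, since reads amplified without molecular identifiers are not independent molecules.

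Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 4 groups, which left 16719 genes with 99.971% of all counts, and libraries were scaled by TMM factors. Levels are counts scaled to a library of 1e6 with the TMM factor (CPM), as the mean and SD of the 2 libraries of a group. Tests were edgeR quasi-likelihood F-tests with robust moderation, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. The comparison of noEGF with EM over both lines used a model with terms for line and medium (5 residual degrees of freedom, biological coefficient of variation 16.9%). The response of each line, the difference of the responses (CTO19 minus apsMC706) and the line difference in each medium (CTO19 minus apsMC706) used a model of the 4 group means, in which all groups shared the estimate of the spread (4 residual degrees of freedom, 4.27%). All tests were two-sided, log2 fold changes are noEGF minus EM unless stated, and SE is the standard error of the log2 fold change.

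A set of 41 gene lists (pathways, cell types and complexes) was tested with camera of limma 3.58.1 on the same models, with a correlation between genes of 0.01, and p-values were adjusted over the 41 lists. Camera compares a list with the other genes. Camera with the correlation estimated for each list, camera on ranks and fry, which tests whether the genes of a list move on balance in 1 direction, were run beside it. For each list the number of members past the threshold over all genes is given beside the number "adjusted over the list alone". List medians with a group at 0 counts were computed a further time with those genes at the floor of 3 counts per library. Folds against a group at 0 counts are lower bounds from the same floor.

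The groups, models, lists, thresholds, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, for the comparison over both lines, the 10 largest log2 fold changes in each direction among genes past the threshold with a mean log2 CPM of at least 3, a gene symbol that is not a placeholder, and libraries that lay apart in both lines. It took 8 in each direction for the other comparisons, up to 4 members per list and direction of smallest p (the 2 of smallest p where none passed), and a fixed set of genes with the 3 targeted genes, receptors and ligands of the EGF family, cell type markers and sex-linked genes. Genes named outside this rule are marked in the text. Chosen after the data were seen were the list tests within each line, 7 added gene lists, the upper-quartile factors for the list tests, the replicate block for the genes shared by the lines, and the list medians with genes at the floor.

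Alternatives changed 1 choice at a time: DESeq2 size factors, upper-quartile factors, no filter on low counts, a stricter filter (1 CPM in at least 4 libraries), limma-voom, the Wald test of DESeq2 1.42.0, moderation that was not robust, mitochondrially encoded genes removed, an adjusted p under 0.01, a test against a fold of 1.5, the replicate number as a block, no line term, summed libraries, the 4 libraries of a comparison alone, and each library left out in turn. Log2 CPM values for the principal components had a prior count of 2. Replicate numbers showed no pairing of libraries across groups: correlations of the differences between replicates, across genes, lay between -0.00825 and 0.0485, and between -0.0209 and 0.0759 for genes with a mean log2 CPM of at least 3.

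The models were tested on simulated data made from these libraries with 50 planted genes per fold. Over both lines, 24% of genes with a 1.1-fold change were recovered, 94% at 1.5-fold and 100% at 2-fold. Of 16427 genes tested, 21 unchanged genes were called. The simulated spread was that of the group means model (4.27%), and both lines were given the same change. These shares therefore do not carry over to the real comparison over both lines, where the coefficient of variation was 16.9%. Within 1 line 82% were recovered at 1.5-fold, and for the difference of the responses also 82%. A planted list was called, and 0 of the other lists were called by camera. Genes were drawn independently of each other, so this does not test the list calls where genes are correlated. Among the 15369 genes with at least 100 counts, 40 had counts identical to those of another gene. Reads of gene families with near-identical members (Zscan4, keratins, Sprr2a, Plac9) could have been assigned to either gene, since their sequences are alike. The same holds for reads of overlapping genes, also on opposite strands, since the kit does not mark the strand. No sample was left out. Ereg, Krt20, Chga and Xist did not pass the filter, and Muc2 was not in the table.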

Results

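RNA was sequenced from mouse colon cancer organoids, self-organising cultures of epithelial cells in which Apc, Trp53 and Smad4 had been disrupted by CRISPR. Apc restrains Wnt signalling, Trp53 encodes the tumour suppressor p53, and Smad4 carries TGF-beta and BMP signals to the nucleus. The 2 lines, apsMC706 (labelled female) and CTO19 (labelled male), were each grown for 3 days in a medium with B27, noggin, galunisertib and EGF (EM) or for 7 days after EGF was left out (noEGF). Noggin blocks BMP ligands and galunisertib inhibits the TGF-beta receptor. Each of the 4 groups held 2 libraries, and the 8 libraries held 35650262 to 38953838 counts each. Mitochondrially encoded genes took 2.94% to 3.68% of counts in EM and 4.13% to 5.19% in noEGF, and the 10 most abundant genes took 4.37% to 6.68%. The lines separated along the component with 79.3% of the variance and the media along the component with 12.7%. Medium went with days in culture and line with labelled sex, so neither pair can be separated. The labels call the 2 lines biological replicates with 2 replicates each, and do not say that these were separate cultures. In the model of the 4 group means, p-values therefore measure the spread between these libraries. Over both lines, the spread also takes in the difference between the responses of the lines. Levels below are the mean CPM with SD over the 2 libraries of a group, gene p-values come from edgeR quasi-likelihood tests and list p-values from limma camera.

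**Figure D1:**
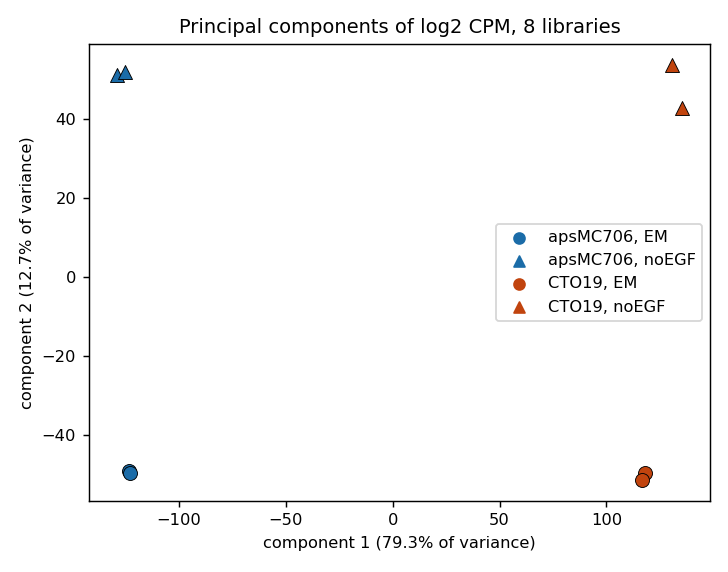
Principal components of log2 CPM for the 8 libraries, with the share of variance on each axis; colours and symbols mark line and medium. The axis with 79.3% of the variance parts apsMC706 from CTO19, and the axis with 12.7% parts EM from noEGF in both lines.

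The comparison of noEGF with EM over both lines asked which genes changed between EM at 3 days and noEGF at 7 days in organoids with this set of mutations. Genes of the dividing cell fell. Anln, a scaffold of the cytokinetic ring (ENSMUSG00000036777, chromosome 9, 22332012 to 22389188 in mm10), was 204 ± 3.31 CPM in EM and 88.2 ± 0.892 in noEGF in apsMC706, and 365 ± 11.4 and 143 ± 9.54 in CTO19, a 2.43-fold lower level (log2 fold change -1.28, SE 0.0616, adjusted p = 4.02e-05, lower in 4 of 4 noEGF libraries). The mitotic kinase Aurka was 2.23-fold lower, the ribonucleotide reductase subunit Rrm2 3.36-fold lower and the replication fork protein Tipin 2.01-fold lower. Mki67, the usual marker of cycling cells, went from 956 to 294 CPM in apsMC706 and from 768 to 466 in CTO19. Of the 34 G2 and M phase genes all 34 fell over all genes tested and 34 adjusted over the list alone (median log2 fold change -1.04, adjusted p = 2.22e-15, adjusted p = 0.315 with an estimated correlation). Of the 34 S phase genes 33 fell over all genes and 34 adjusted over the list alone (median -1.01, adjusted p = 1.93e-10, adjusted p = 0.407 with an estimated correlation).

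Growth and sterol synthesis fell with them. Rrp12, a ribosome export factor, was 2.27-fold lower (log2 fold change -1.18, SE 0.0767, adjusted p = 7.84e-05), and the nucleolar chaperone Nolc1 was 1.73-fold lower. In the ribosome biogenesis list 35 of 40 genes fell and 0 rose (36 fell adjusted over the list alone, median -0.65, adjusted p = 7.73e-16, adjusted p = 0.137 with an estimated correlation). Dhcr7, the last enzyme of cholesterol synthesis, had a log2 fold change of -0.58 (SE 0.0638, adjusted p = 0.000437). Of the 26 cholesterol synthesis genes 16 fell and 0 rose, and 16 fell adjusted over the list alone (median -0.35, adjusted p = 2.14e-05, adjusted p = 0.36 with an estimated correlation). In oxidative phosphorylation 13 of 40 genes fell and 2 rose (12 and 2 adjusted over the list alone, median -0.16). Cytochrome c (Cycs) was 1.53-fold lower and Ndufa6 1.56-fold higher, while the mitochondrial share of counts was higher in noEGF, as given above. This call (adjusted p = 0.0148) was lost with fry (adjusted p = 0.0823) and with an estimated correlation (adjusted p = 0.72). Within the lines the list passed in apsMC706 (5 rose, 31 fell, also adjusted over the list alone, median -0.32, adjusted p = 5.9e-05, adjusted p = 0.577 with an estimated correlation) and not in CTO19 (8 rose, 11 fell, adjusted p = 0.844).

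Interferon-induced and antigen presentation genes rose. Ifit1, an antiviral RNA sensor, was 5.96-fold higher (log2 fold change 2.58, SE 0.224, adjusted p = 0.000204), going from 0.604 ± 0.0314 to 2.82 ± 0.0882 CPM in apsMC706 and from 1.67 ± 0.146 to 12.1 ± 4.23 in CTO19. Oasl2 rose by 2.14 on the log2 scale, and the MHC class I genes H2-T23 and B2m were 2.76-fold and 1.64-fold higher. Of the 35 interferon genes 30 rose and 0 fell, with 30 and 0 adjusted over the list alone (median 1.86, adjusted p = 4.99e-08, adjusted p = 0.322 with an estimated correlation). Of the 17 antigen presentation genes 15 rose over all genes and 16 adjusted over the list alone (median 0.98, adjusted p = 2.14e-05, adjusted p = 0.234 with an estimated correlation).

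FOXO targets and lysosomal genes rose as well. Erbb3, a receptor of the EGF family that FOXO factors induce (ENSMUSG00000018166, chromosome 10, 128567523 to 128589652), went from 81.8 ± 0.0827 to 192 ± 1.19 CPM in apsMC706 and from 67.7 ± 1.65 to 157 ± 5.20 in CTO19 (2.34-fold, log2 fold change 1.23, SE 0.0474, adjusted p = 2e-05, higher in 4 of 4 noEGF libraries). Fbxo32, a ubiquitin ligase of protein breakdown, was 5.30-fold higher and Foxo3 1.75-fold higher, while catalase (Cat), also on the list, was 1.70-fold lower. Among the 28 FOXO targets 19 rose and 1 fell over all genes, and 21 and 1 adjusted over the list alone (median 0.82, adjusted p = 5.66e-06, adjusted p = 0.2 with an estimated correlation). The autophagy gene Map1lc3a was 2.52-fold and the lysosomal membrane protein Lamp2 1.57-fold higher. Of the 35 lysosome and autophagy genes 22 rose and 1 fell, and the same numbers adjusted over the list alone (median 0.46, adjusted p = 2.33e-05, adjusted p = 0.13 with an estimated correlation).

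Markers of differentiated intestinal cells rose, to different levels in the lines. Mmp7, a protease of Paneth cells, went from 48.2 ± 1.23 to 790 ± 25.4 CPM in apsMC706 and from 19.2 ± 2.05 to 93.2 ± 16.9 in CTO19 (8.98-fold, log2 fold change 3.17, SE 0.376, adjusted p = 0.000626), and it shares its position with AV064505. Agr2, a protein disulphide isomerase of mucus cells, was 2.51-fold and Cd24a 2.71-fold higher. The mucin gene Muc13 went from 1.86 to 63.9 CPM in apsMC706 and was at 0.13 and 0.734 CPM in CTO19, whose own test gave an adjusted p of 0.0651. Atoh1, the regulator of the secretory fate, was 15.5-fold lower, from 3.62 to 0.202 CPM in apsMC706, and lay under the level that 3 counts allow in CTO19. Of the 15 Paneth genes 13 rose (13 adjusted over the list alone, median 1.68, adjusted p = 0.000212, adjusted p = 0.137 with an estimated correlation). Of the 25 goblet genes 14 rose and 2 fell (15 and 2 adjusted over the list alone, median 0.89, adjusted p = 0.00438, adjusted p = 0.315 with an estimated correlation). Within the lines the goblet list passed in CTO19 (14 rose, 2 fell, also adjusted over the list alone, median 1.09, adjusted p = 0.00555, adjusted p = 0.219 with an estimated correlation) and not in apsMC706 (13 rose, 5 fell, adjusted p = 0.0521). The difference between the lines did not pass (11 higher and 2 lower in CTO19, adjusted p = 0.284). Of the 21 absorptive genes, such as Ceacam1 with a 2.00-fold higher level, 10 rose and 1 fell (11 and 1 adjusted over the list alone, median 1.09, adjusted p = 0.00494, adjusted p = 0.184 with an estimated correlation).

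Wnt and BMP targets, junctions and fatty acid oxidation rose in part of their members. The secreted Wnt inhibitors Wif1 and Dkk2 were 6.91-fold and 6.47-fold higher, and the Wnt effector Tcf7 was 1.33-fold lower. Of 28 Wnt targets 17 rose and 2 fell, also adjusted over the list alone (median 0.78, adjusted p = 0.00201, adjusted p = 0.315 with an estimated correlation). Bmp2 was 3.16-fold higher (log2 fold change 1.66, SE 0.102). Of 24 BMP and TGF-beta targets 10 rose and 2 fell, also adjusted over the list alone (median 0.47, adjusted p = 0.0301, adjusted p = 0.315 with an estimated correlation). The claudin Cldn23 was 6.64-fold higher. Of 26 tight junction genes 12 rose and 1 fell, also adjusted over the list alone (median 0.47, adjusted p = 0.0035, adjusted p = 0.374 with an estimated correlation). Within the lines that list passed in CTO19 (22 rose, 2 fell, 22 and 3 adjusted over the list alone, median 0.62, adjusted p = 2.47e-06, adjusted p = 0.193 with an estimated correlation) and not in apsMC706 (13 rose, 5 fell, adjusted p = 0.133). Of 25 fatty acid oxidation genes 12 rose and 2 fell, also adjusted over the list alone (median 0.53, adjusted p = 0.0104, adjusted p = 0.36 with an estimated correlation). Within the lines fatty acid oxidation passed in CTO19 (19 rose, 3 fell, also adjusted over the list alone, adjusted p = 0.000757, adjusted p = 0.219 with an estimated correlation) and not in apsMC706 (10 rose, 9 fell, adjusted p = 0.555). The test of the difference between the lines did not pass (12 higher and 2 lower in CTO19, median 0.53, adjusted p = 0.0517, adjusted p = 0.393 with an estimated correlation), but it did with DESeq2 size factors (0.0435) and upper-quartile factors (0.0399).

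Among the largest changes, Gkn3, a gastrokine, went from 0.593 ± 0.202 to 31.6 ± 0.708 CPM in apsMC706 and from 0 to 8 counts in CTO19 (log2 fold change 5.73, SE 0.356, adjusted p = 7.31e-05). Ugt2b35, a glucuronosyltransferase, was 23.3-fold higher, from 1.18 to 30.0 CPM and from 0.185 to 3.60 CPM. The calmodulin-like Calml3 (5.05), the epidermal keratin Krt1 (4.91), Krt73 (4.54), Prr9 (4.51), Dsc1 (4.24), Rp1 (4.21) and Nccrp1 (3.96) were also among the largest increases on the log2 scale, and their levels in noEGF were higher in CTO19 than in apsMC706. Downward, Pcolce2, an enhancer of collagen processing, was 5.71-fold lower (-2.51, SE 0.0927, adjusted p = 1.77e-05). Zscan4a to Zscan4f, genes active in early embryos whose reads cannot be assigned with certainty, were 4.58-fold to 4.86-fold lower, and Plac9a and Plac9b were 4.01-fold and 3.98-fold lower. Hmga2, a chromatin protein of fetal and tumour cells, was 3.79-fold lower (adjusted p = 0.022). Its call was lost without CTO19 noEGF replicate 1 (adjusted p = 0.0824) or replicate 2 (adjusted p = 0.0975) and with the replicate block (adjusted p = 0.081).

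Of the genes fixed by name, Lgr5, a Wnt target of stem cells, was 1.64-fold higher (adjusted p = 0.00861) and the tuft cell kinase Dclk1 2.69-fold lower (adjusted p = 0.000314). The apsMC706 libraries held Lgr5 at 170 and 163 CPM in EM and 290 and 310 in noEGF. Those of CTO19 held it at 15 and 13.5 CPM in EM and 15.7 and 26.5 in noEGF, so that rise came largely from replicate 2. Egfr was 1.56-fold higher over both lines, with 14.9 and 33.1 CPM in apsMC706 and 73.7 and 81.8 CPM in CTO19 (log2 fold change 0.64, adjusted p = 0.0352). That call was lost without apsMC706 EM replicate 1 (adjusted p = 0.101) or 2 (0.104), apsMC706 noEGF replicate 1 (0.0782) or 2 (0.0762), or CTO19 EM replicate 2 (0.0653), and with the replicate block (0.0937). Erbb2, which overlaps Mien1, was 1.31-fold higher (adjusted p = 0.0393), and its call was lost without apsMC706 EM replicate 2 (0.0572), CTO19 EM replicate 1 (0.114) or 2 (0.118), and with the replicate block (0.119). Its rise was in CTO19, from 85.9 and 89.9 CPM in EM to 145 and 142 in noEGF. In apsMC706 the libraries overlapped, at 64.8 and 60.6 CPM in EM and 64.6 and 67 in noEGF. The EGFR ligand Areg had a log2 fold change of -0.73 that did not pass the test (adjusted p = 0.295). It was -1.13 without apsMC706 EM replicate 2, and -0.25 and -0.28 without CTO19 noEGF replicates 1 and 2.

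In all, 8157 of 16719 genes passed the threshold, 4265 higher and 3892 lower, of which 1946 and 685 changed at least 2-fold, and 17 of 41 lists did. These lists include the Y-linked genes, whose result rests on CTO19, as given below. The ERK target list (9 rose, 6 fell of 30, adjusted p = 0.427), the EGF family (10 and 5 of 20, 0.315), stem cell genes (13 and 3 of 24, 0.0528), cell cycle inhibitors (13 and 5 of 25, 0.0576), NF-kB genes (11 and 2 of 32, 0.0576), the fetal and YAP genes (9 and 3 of 31, 0.232), fatty acid synthesis (4 and 11 of 22, 0.083), mesenchymal (4 and 8 of 17, 0.0626), squamous and gastric (8 and 2 of 23, 0.0732), cell death (15 and 6 of 29, 0.104) and hypoxia genes (8 and 3 of 24, 0.189) did not pass. Nor did the ribosomal proteins (0 and 5 of 48, 0.169), glycolysis (2 and 7 of 20, 0.427), tuft cells (5 and 3 of 19, 0.427), Notch (5 and 2 of 16, 0.725), enteroendocrine cells (3 and 2 of 9, 0.822), the unfolded protein response (7 and 5 of 26, 0.858), p53 targets (8 and 6 of 31, 0.858), histones (3 and 4 of 17, 0.915) and ATF4 genes (10 and 11 of 37, 0.983). Markers of fibroblasts (3 and 0 of 11, 0.357), immune cells (5 and 0 of 7, 0.0576), and endothelial, glial and muscle cells (3 and 0 of 8, 0.243) did not pass either, nor did mitochondrially encoded genes (3 and 0 of 13, 0.0552), which passed with DESeq2 size factors (0.0491) and upper-quartile factors (0.0468). Stem cell genes passed with the same 2 (0.0491 and 0.0468), and mesenchymal genes with upper-quartile factors (0.047) but not with DESeq2 size factors (0.051). The gene count was 5096 with replicate number as a block (2719 higher, 2377 lower) and 2221 against a fold of 1.5 (1558 and 663). It was 1806 with no line term (743 and 1063) and 84 with the libraries of each line and medium summed (83 and 1). Only the summed libraries have the line as the unit of replication. All but 1 of the 3892 genes called lower lost their call there. With an estimated correlation camera called 0 of 41 lists (6 at an unadjusted p under 0.05) while fry called 30.

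Within the lines the proliferation genes fell in each: of 68 S phase and G2 and M phase genes, 68 fell in apsMC706 and 66 in CTO19. With an estimated correlation camera called 0 of 41 lists in either line. The genes with the largest changes differed between the lines, though some changed in both. In apsMC706, Notch3, a Notch receptor, went from 0.201 ± 0.0149 to 7.03 ± 0.411 CPM (log2 fold change 5.10, SE 0.221, adjusted p = 5.59e-11), and Gsdma, a pore-forming gasdermin, from 16.2 ± 0.257 to 1.29 ± 0.0848 CPM (-3.65, SE 0.135). Its largest increases further held Muc13 (5.10), Gkn3 (5.74) and H19, an imprinted RNA that overlaps Mir675 (3 to 115 counts in the group). They also held Pglyrp4, Zfp750, Wnt7a and Ltf, which had 0 counts in EM and rose at least 4.17-fold, 3.64-fold, 1.99-fold and 1.67-fold. Klk10 fell by 3.40 on the log2 scale, Zscan4a to Zscan4d and Zscan4f had log2 fold changes of -3.39 (Zscan4b) to -3.68 (Zscan4d), and Rab38 went from 4 to 0 counts in the group (adjusted p = 0.0289), a call lost without any of the 4 apsMC706 libraries (adjusted p = 0.0586, 0.0615, 0.107 and 0.112 without EM replicates 1 and 2 and noEGF replicates 1 and 2).

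In CTO19, Nts, the precursor of the gut hormone neurotensin, went from 4.41 ± 0.00787 to 395 ± 47.1 CPM (log2 fold change 6.48, SE 0.104, adjusted p = 1.64e-11), and genes of the cornified layer of skin had the other large increases: Spink12 (7.08), Lce1a1 (6.21), Hrnr (6.18), Klk14 (5.93), Kprp (5.48) and Calml3 (5.30). Hoxb13 had 0 counts in EM and rose at least 2.96-fold, to 0.254 CPM. The cytokine gene Il24 went from 32.2 to 2.16 CPM, the stromelysin Mmp3 from 41.0 to 3.85, the protein C receptor Procr from 299 to 50.6 and Hmga2 from 157 to 16.9 CPM, and Thbs2, Pcolce2, Emp3 and Enpp1 had log2 fold changes of -2.75, -2.60, -2.51 and -2.46. In apsMC706 11236 genes passed the threshold (5704 higher, 5532 lower) and in CTO19 11376 (5801 higher, 5575 lower). The counts were 4331 and 3641 against a fold of 1.5. The split moved with the processing: 6383 higher and 4851 lower in apsMC706 with upper-quartile factors, and 5832 and 5879 in CTO19 with no filter on low counts.

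Genes called in both lines in the same direction numbered 5951, against 3823.8 from independent calls. Of these 2858 were higher and 3093 lower, with Erbb3, Pcolce2 and Anln among them. Genes called in opposite directions numbered 2220, against 3821.5 from independent calls, with Gsdma, Vegfa and Myc among them. Across genes, which are not independent replicates, the log2 fold changes of the lines correlated with a Pearson r of 0.312 and a Spearman rho of 0.377. Of the 8157 genes called over both lines, 5888 (72.2%) were called in the same direction in each line and 4 in opposite directions.

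The difference of the responses asked where the 2 lines reacted unlike each other. Targets of ERK, the kinase downstream of EGF receptors, moved apart. Dusp6, a phosphatase that ERK induces and that dampens it (ENSMUSG00000019960, chromosome 10, 99263231 to 99267489), went from 144 ± 0.26 to 215 ± 2.91 CPM in apsMC706 and from 84.7 ± 4.26 to 31.6 ± 1.18 in CTO19 (difference of log2 fold changes -2.003, SE 0.0647, adjusted p = 1.39e-11). Myc rose by 0.94 in apsMC706 and fell by 0.71 in CTO19, and Emp1 rose by 1.31 and fell by 0.67. The differences were -1.35 for the cyclin Ccnd1, which overlaps LTO1, and 0.75 for the survival gene Mcl1, which went the other way. Of 30 ERK targets 24 had a lower and 2 a higher response in CTO19, also adjusted over the list alone (median -1.17, adjusted p = 8.29e-10, adjusted p = 0.0717 with an estimated correlation). Within the lines the list median was 0.70 in apsMC706 (19 rose, 5 fell, 19 and 6 adjusted over the list alone, adjusted p = 0.0013, adjusted p = 0.222 with an estimated correlation) and -0.39 in CTO19 (10 rose, 17 fell, also adjusted over the list alone, adjusted p = 0.0295, adjusted p = 0.219 with an estimated correlation). The EGFR ligands Areg (0.70 in apsMC706, -1.98 in CTO19) and Hbegf (difference -1.95) also moved apart.

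**Figure D2:**
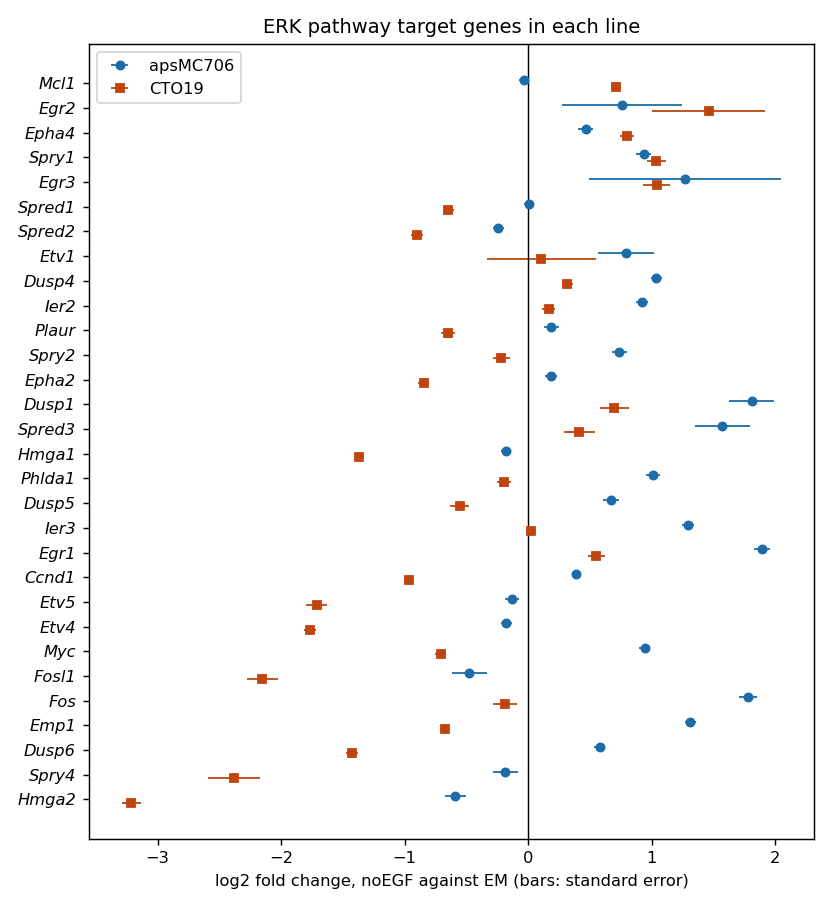
Log2 fold change of noEGF over EM for the 30 ERK pathway target genes in each line, with error bars of 1 SE, sorted by the difference between the lines. Dusp6 lies at 0.58 in apsMC706 and at -1.43 in CTO19, and the list medians are 0.70 and -0.39.

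The EGF family list as a whole had 8 lower and 2 higher of 20, also adjusted over the list alone (median -0.35, or -0.45 with genes at the floor, adjusted p = 0.0432, adjusted p = 0.564 with an estimated correlation). Its call was lost without apsMC706 EM replicate 1 (0.0601), apsMC706 noEGF replicate 2 (0.0554), CTO19 EM replicate 1 (0.0984) or CTO19 noEGF replicate 1 (0.0679).

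Genes of low oxygen, glycolysis and inflammation also had lower responses in CTO19. Vegfa, the blood vessel growth factor (chromosome 17, 46016993 to 46032369), went from 29.9 ± 0.328 to 126 ± 0.662 CPM in apsMC706 and from 15.3 ± 0.403 to 3.63 ± 0.314 in CTO19 (difference -4.16, SE 0.0904, adjusted p = 2.33e-13). P4ha1, a collagen prolyl hydroxylase, went from 13.2 to 73.7 and from 42.9 to 13.2 CPM, and the glycolytic Pgk1 from 616 to 1479 and from 680 to 349. Of 24 hypoxia genes 17 had a lower and 3 a higher response in CTO19, also adjusted over the list alone (median -1.38, adjusted p = 5.3e-07, adjusted p = 0.258 with an estimated correlation). Of 20 glycolysis genes 16 were lower and 1 higher, also adjusted over the list alone (median -0.86, adjusted p = 2.52e-08, adjusted p = 0.32 with an estimated correlation). The NF-kB inhibitors Nfkbia and Tnfaip3 differed by -1.61 and -2.22 and Tnf by -2.39. Of 32 NF-kB genes 21 were lower and 3 higher, also adjusted over the list alone (median -1.87, or -1.60 with genes at the floor, adjusted p = 3.96e-05, adjusted p = 0.258 with an estimated correlation). Anxa8 and the muscle-type YAP target Ankrd1 differed by -2.03 and -4.21, Clu by 2.08. Of 31 fetal and YAP genes 22 were lower and 2 higher over all genes and 23 and 2 adjusted over the list alone (median -1, or -0.84 with genes at the floor, adjusted p = 2.53e-06, adjusted p = 0.464 with an estimated correlation). Within apsMC706 the hypoxia (19 rose, 5 fell, adjusted p = 3.51e-05, adjusted p = 0.247 with an estimated correlation), NF-kB (22 and 1, adjusted p = 7.94e-05, adjusted p = 0.247 with an estimated correlation) and fetal and YAP lists (21 and 1, adjusted p = 7.76e-05, adjusted p = 0.435 with an estimated correlation) rose, with the same numbers adjusted over the list alone. In CTO19 hypoxia (8 rose, 12 fell, adjusted p = 0.25), NF-kB (13 and 12, adjusted p = 0.844) and fetal and YAP genes (10 and 15, adjusted p = 0.424) did not pass. Glycolysis fell in CTO19 (3 rose, 16 fell, 4 and 16 adjusted over the list alone, adjusted p = 9.44e-05, adjusted p = 0.243 with an estimated correlation) and did not pass in apsMC706 (11 and 7, adjusted p = 0.0803).

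Ribosomal protein genes and genes of the unfolded protein response and of ATF4 rose in apsMC706 and fell in CTO19. All but 1 of the 48 ribosomal protein genes had a lower response in CTO19 (47 lower, 0 higher over all genes, 47 and 1 adjusted over the list alone, median -0.64, adjusted p = 2.25e-18, adjusted p = 0.464 with an estimated correlation). Hspa5, a chaperone of the endoplasmic reticulum, rose by 0.94 and fell by 0.67. Of 26 genes of the unfolded protein response 19 were lower and 2 higher, also adjusted over the list alone (median -0.58, adjusted p = 3.13e-08, adjusted p = 0.32 with an estimated correlation). The translation repressor Eif4ebp1 and the lipoprotein receptor Vldlr differed by -1.53 and -2.56. Of 37 ATF4 genes 28 were lower and 3 higher over all genes and 28 and 4 adjusted over the list alone (median -0.76, adjusted p = 1.23e-08, adjusted p = 0.32 with an estimated correlation). Within the lines the ribosomal proteins had 37 higher and 5 lower in apsMC706 (37 and 6 adjusted over the list alone, adjusted p = 1.26e-05, adjusted p = 0.577 with an estimated correlation) and 47 lower in CTO19 (47 adjusted over the list alone, adjusted p = 5.99e-12, adjusted p = 0.39 with an estimated correlation). The unfolded protein response had 19 higher and 4 lower (adjusted p = 0.00194, adjusted p = 0.435 with an estimated correlation) and 6 higher and 17 lower (adjusted p = 0.00131, adjusted p = 0.355 with an estimated correlation). ATF4 genes had 24 higher and 9 lower (adjusted p = 0.00386, adjusted p = 0.464 with an estimated correlation) and 7 higher and 21 lower (adjusted p = 0.00479, adjusted p = 0.427 with an estimated correlation), with the same numbers for both lists adjusted over the list alone.

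S phase and G2 and M phase genes fell in both lines and fell more in apsMC706. The DNA primase Prim1 had log2 fold changes of -2.02 in apsMC706 and -0.46 in CTO19, and the mitotic motor Kif11 -1.49 and -0.52. Of 34 S phase genes 33 had a higher response in CTO19 (33 adjusted over the list alone, median 0.98, adjusted p = 7.11e-14, adjusted p = 0.32 with an estimated correlation), and of 34 G2 and M phase genes 32 (32 adjusted over the list alone, median 0.59, adjusted p = 7.24e-09, adjusted p = 0.464 with an estimated correlation). Of 26 cholesterol synthesis genes 16 were higher and 4 lower (17 and 4 adjusted over the list alone, median 0.24, adjusted p = 0.00429, adjusted p = 0.636 with an estimated correlation). Ndufa4 differed by 1.25. Of 40 genes of oxidative phosphorylation 27 were higher and 3 lower (28 and 4 adjusted over the list alone, median 0.26, adjusted p = 0.000279, adjusted p = 0.79 with an estimated correlation). Occludin (Ocln) differed by 0.85. Of 26 tight junction genes 17 were higher and 5 lower, also adjusted over the list alone (median 0.47, adjusted p = 0.0073, adjusted p = 0.32 with an estimated correlation).

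**Figure D3:**
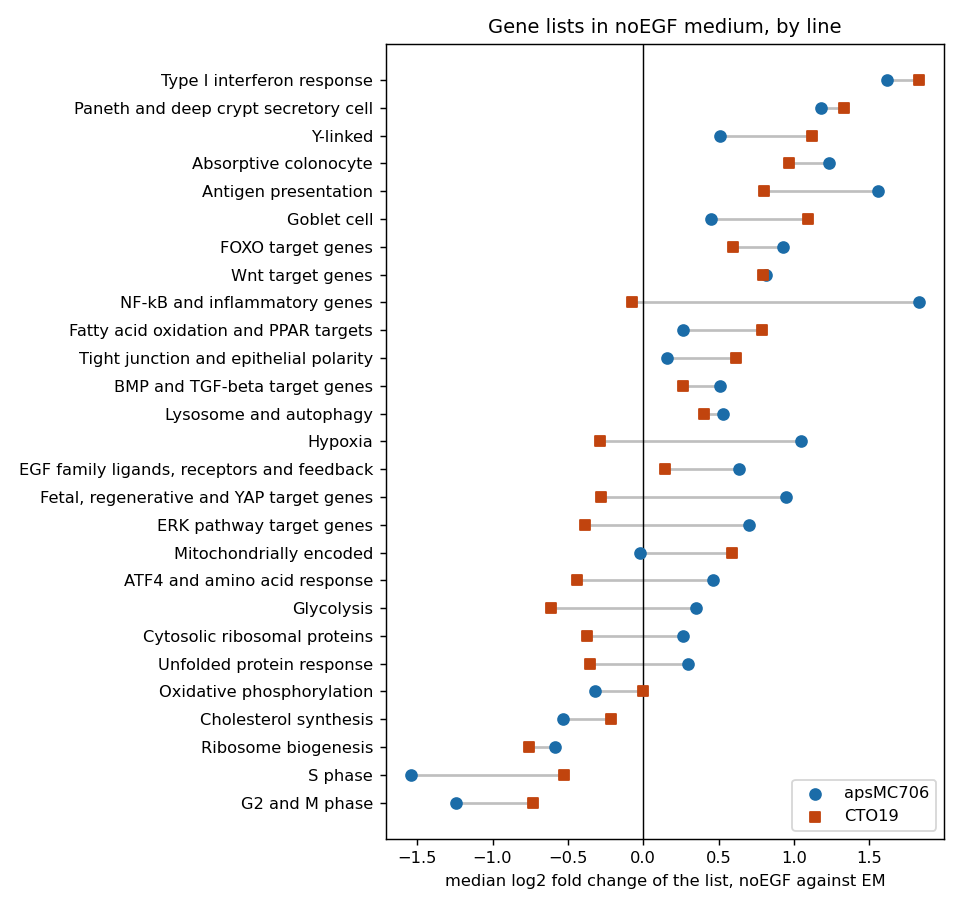
Median log2 fold change of noEGF over EM in apsMC706 and in CTO19 for the 27 gene lists past the threshold over both lines or in the difference of the responses. S phase genes lie at -1.54 and -0.52, ERK targets at 0.70 and -0.39 and hypoxia genes at 1.05 and -0.29.

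The last 3 lists had differences that some settings did not keep. Of 13 mitochondrially encoded genes 6 were higher and 0 lower over all genes, 5 and 0 adjusted over the list alone, with mt-Nd3 at 0.74 (median 0.65, adjusted p = 0.0297, adjusted p = 0.793 with an estimated correlation). That call was lost with fry (0.109) and without apsMC706 EM replicate 1 (0.0549), apsMC706 noEGF replicate 2 (0.0554), CTO19 EM replicate 2 (0.0561) or CTO19 noEGF replicate 1 (0.0504). Of 28 FOXO targets 13 were lower, Klf6 by -1.44, and 5 higher, Ccng2 by 0.77, also adjusted over the list alone (median -0.18, adjusted p = 0.0496, adjusted p = 0.464 with an estimated correlation). That call was lost on ranks (0.0617) and without apsMC706 EM replicate 1 (0.0509) or 2 (0.0527), apsMC706 noEGF replicate 2 (0.0509), CTO19 EM replicate 1 (0.0984) or CTO19 noEGF replicate 1 (0.0696). Of 40 ribosome biogenesis genes 19 were lower, Nop16 by -0.82, and 6 higher, Utp20 by 0.61, also adjusted over the list alone (median -0.10, adjusted p = 0.0354, adjusted p = 0.79 with an estimated correlation). That call was lost without apsMC706 EM replicate 1 (0.0513) or noEGF replicate 2 (0.0647).

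The responses of 9366 genes differed between the lines, 5083 with a higher and 4283 with a lower response in CTO19. The larger side was the higher in the main analysis, and the sides were even with DESeq2 size factors (50% higher). The lower side was the larger with upper-quartile factors (47.82% higher), with no filter on low counts (46.93%) and with the stricter filter (47.1%). It was also the larger when either CTO19 noEGF library was left out, so the larger side is not settled. Against a fold of 1.5 the count was 3194. Gsdma had the highest difference (6.79, adjusted p = 9.48e-13), with Hoxb13, Nts, Krt10, Rbp2 and Tgfb2 among the next. Wnt7a (-7.15, which depends on the prior count), Il24 (-6.22), Tnc (-5.82), Ngfr (-5.72), Mmp13 (-5.64) and Slc16a3 (-5.59) were among the lowest.

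The line difference in EM asked how the 2 lines compare before EGF was withdrawn. CTO19 carried squamous genes at high levels and several intestinal genes at low levels. Trp63, the master regulator of stratified epithelium (ENSMUSG00000022510, chromosome 16, 25683763 to 25892102), was 130 ± 0.315 CPM in CTO19 and 0.0537 ± 0.0011 in apsMC706 (log2 difference 11.16, SE 0.162, adjusted p = 5.71e-16). Lypd3, a surface protein of squamous cells, was 350-fold higher and Krt15 26.5-fold higher. The basal keratins Krt5 and Krt14, named after their values were seen, were 3792 and 3481 CPM in CTO19 and 1.60 and 1.36 in apsMC706. Cdh17, an intestinal cadherin, Lgals4 and Hnf4a, also named after their values were seen, were 336, 399 and 70.8 CPM in apsMC706 and 1.26, 8.75 and 0.0707 in CTO19. Of 23 squamous and gastric genes 15 were higher and 5 lower, also adjusted over the list alone (median 2.76, adjusted p = 0.0268, adjusted p = 0.479 with an estimated correlation).

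**Figure D4:**
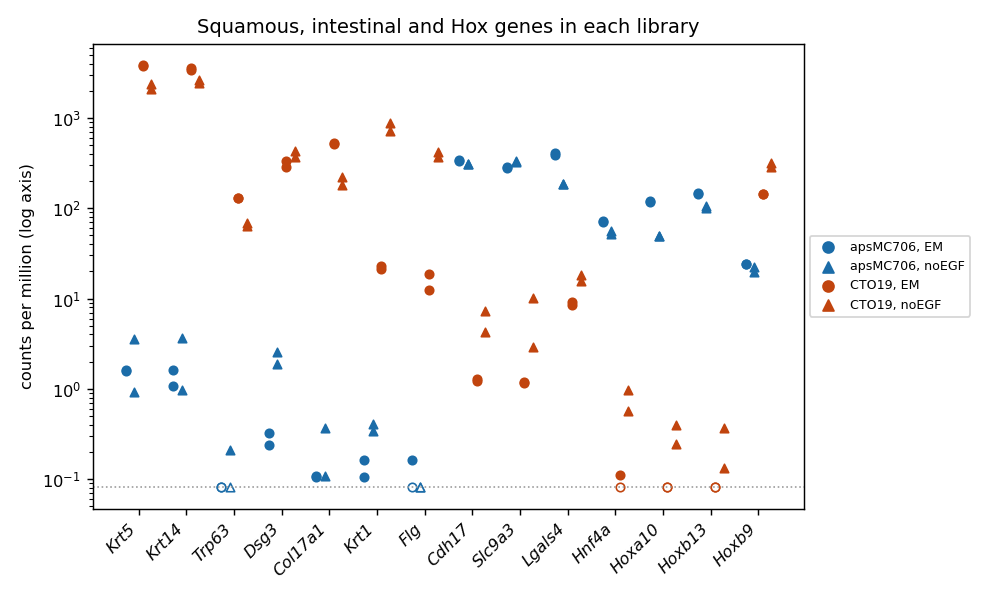
CPM of squamous, intestinal and Hox genes in each of the 8 libraries on a log axis; open symbols are at or under 3 counts and the dotted line marks that level. Krt5 lies at a mean of 3792 CPM in CTO19 EM and 1.60 CPM in apsMC706 EM, and Cdh17 at 1.26 and 336 CPM; most of these genes were chosen after their values were seen.

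Inflammatory, fetal and mesenchymal genes were higher in CTO19. Tnfaip2 was 217 CPM in CTO19 and 0.108 in apsMC706, the interleukin gene Il1a was 530-fold and Nfkbia 5.80-fold higher, and Cxcl10 was 2.42-fold lower. Of 32 NF-kB genes 31 were higher and 1 lower, also adjusted over the list alone (median 5.08, or 4.10 with genes at the floor, adjusted p = 3.25e-09, adjusted p = 0.417 with an estimated correlation). Emp1 was 7.14-fold and Anxa8 10.9-fold higher. Of 31 fetal and YAP genes 25 were higher and 2 lower, also adjusted over the list alone (median 1.63, adjusted p = 1.79e-07, adjusted p = 0.479 with an estimated correlation). The transcription factor Snai2 and the matrix gene Sparc were higher by 10.66 and 8.87 on the log2 scale, while vimentin (Vim, -4.50) and Mmp14 (-7.26) were lower. Of 17 mesenchymal genes 13 were higher and 3 lower, also adjusted over the list alone (median 2.86, adjusted p = 0.0268, adjusted p = 0.479 with an estimated correlation). Id3 and Bmp7 were 9.13-fold and 5.16-fold higher and Bambi 7.72-fold lower. Of 24 BMP and TGF-beta targets 19 were higher and 3 lower, also adjusted over the list alone (median 1.25, or 1.08 with genes at the floor, adjusted p = 0.00332, adjusted p = 0.479 with an estimated correlation). Hist1h1c was 2.14-fold higher. Of 17 histone genes 11 were higher and 0 lower, also adjusted over the list alone (median 1.20, adjusted p = 0.0431, adjusted p = 0.541 with an estimated correlation). The libraries were poly(A)-selected, so these values cover only the histone RNA kept by that selection and cannot give total histone expression. The histone call was lost on ranks (0.0522) and without apsMC706 EM replicate 2 (0.0513) or CTO19 EM replicate 1 (0.0665).

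Stem cell, goblet and growth genes were lower in CTO19. Prom1 was 856 CPM in apsMC706 and 174 in CTO19, and the receptor gene Tnfrsf19 was 4.65-fold lower, while Cd44 was 2.68-fold higher. Of 24 stem cell genes 17 were lower and 6 higher, also adjusted over the list alone (median -0.94, adjusted p = 0.002, adjusted p = 0.507 with an estimated correlation). Creb3l1 and Agr2 were 147-fold and 21.9-fold lower. Of 25 goblet genes 16 were lower and 7 higher, also adjusted over the list alone (median -1.10, adjusted p = 0.0451, adjusted p = 0.479 with an estimated correlation). The goblet call was lost with DESeq2 size factors (0.0503), upper-quartile factors (0.0545) and without CTO19 EM replicate 1 (0.0882) or 2 (0.101). Paneth (4 higher, 9 lower of 15, adjusted p = 0.367), enteroendocrine (3 and 3 of 9, 0.984) and tuft cell genes (13 and 2 of 19, 0.12) did not pass. Pcna was 2.38-fold and Aurka 1.70-fold lower. Lower were 21 of 34 S phase genes and higher 7, also adjusted over the list alone (median -0.21, adjusted p = 0.0163, adjusted p = 0.694 with an estimated correlation). Of 34 G2 and M phase genes 28 were lower and 3 higher, also adjusted over the list alone (median -0.41, adjusted p = 2.06e-05, adjusted p = 0.541 with an estimated correlation). Lower also were 25 of 37 ATF4 genes (6 higher, median -0.34, adjusted p = 0.00483, adjusted p = 0.541 with an estimated correlation), such as Trib3 at -2.67, and 28 of 40 genes of oxidative phosphorylation (4 higher, median -0.24, adjusted p = 0.00029, adjusted p = 0.694 with an estimated correlation), such as Cyc1 at -0.80. The same held for 22 of 40 ribosome biogenesis genes (6 higher, median -0.17, adjusted p = 0.02, adjusted p = 0.7 with an estimated correlation), such as Nat10 at -1.32, and for 30 of 48 ribosomal protein genes (4 higher, median -0.15, adjusted p = 0.00225, adjusted p = 0.763 with an estimated correlation), such as Rpl23 at -1.16. Adjusted over the list alone, those 4 lists had 25, 28, 22 and 30 lower and 6, 4, 6 and 3 higher.

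The largest differences in EM were of genes with few or no counts in a line. Kirrel, Bnc1, Oaf, Arhgdib (which overlaps Pde6h), Tmprss11e and Dynap had 0 counts in apsMC706 and were at least 1120-fold, 973-fold, 935-fold, 904-fold, 901-fold and 608-fold higher in CTO19, Trib2 was at least 474-fold higher, and the actin bundler Fscn1 was 236 CPM against 1 count. Hoxb13, a marker of the most posterior gut, was 145 ± 2.27 CPM in apsMC706 and had 0 counts in CTO19 (at least 1690-fold lower), and Hoxa11os, which overlaps Hoxa11, was at least 377-fold lower. Insm1 (84.6 and 0.029 CPM), Hoxa10 (119 and 0.043), Tnfrsf11b (130 and 0.0575), Mdga2 (35.7 and 0.0141), Egflam (34.9 and 0.0145) and Cers4 (31.3 and 0.0141) were also lower in CTO19. In EM 11921 genes differed between the lines (6273 higher and 5648 lower in CTO19), 5537 against a fold of 1.5. Lists of markers of fibroblasts (6 higher, 1 lower of 11, adjusted p = 0.162), immune cells (5 and 0 of 7, 0.0724) and endothelial, glial and muscle cells (3 and 2 of 8, 0.934) did not pass. In noEGF 13375 genes differed (7640 higher and 5735 lower), 7293 against a fold of 1.5. The sides were closer with upper-quartile factors (6953 higher, 6420 lower) and with the stricter filter (5851 and 5539).

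The targeted genes were read in every library. Apc (chromosome 18, 34220924 to 34322552) was 195 ± 4.70 CPM in EM and 178 ± 1.26 in noEGF in apsMC706, and 64.3 ± 6.34 and 78.1 ± 0.0931 in CTO19. Smad4 (chromosome 18, 73639009 to 73703780) was 34.0 ± 0.432 and 39.4 ± 0.628 CPM, and 11.8 ± 1.48 and 18.6 ± 0.708. Trp53 (chromosome 11, 69580359 to 69591873) was 14.7 ± 2.37 and 15.2 ± 0.249 CPM, and 30.8 ± 3.47 and 29.7 ± 0.024. Over both lines Smad4 was 1.34-fold higher in noEGF (adjusted p = 0.0145, lost with the replicate block at 0.0639), and Apc (adjusted p = 0.564) and Trp53 (adjusted p = 0.978) did not pass. No unedited organoids were among the samples, and an edit need not lower the count of a transcript.

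Y-linked genes were read in CTO19, labelled male, and almost not in apsMC706, labelled female. The 7 Y-linked genes summed to 11 to 17 counts in each apsMC706 library and to 2480, 2514, 5319 and 6259 in the CTO19 libraries, the larger sums in noEGF. Within CTO19 all 4 measured Y-linked genes rose (4 adjusted over the list alone, median log2 fold change 1.12, adjusted p = 0.00576, adjusted p = 0.219 with an estimated correlation), with Ddx3y going from 21.6 ± 0.434 to 40.0 ± 2.13 CPM and Eif2s3y from 28.1 ± 0.128 to 56.4 ± 2.20. Over both lines 3 of the 4 rose (3 adjusted over the list alone, median 1.12, adjusted p = 0.0184, adjusted p = 0.315 with an estimated correlation), and between the lines in EM all 4 were higher in CTO19 (4 adjusted over the list alone, median 7.95, adjusted p = 0.0268, adjusted p = 0.479 with an estimated correlation). With almost no Y-linked counts in apsMC706, the result over both lines rests on CTO19 and shows no response of apsMC706. Xist, the RNA that silences an X chromosome in female cells, had 3 to 9 counts in every library and 4 to 6 in those of apsMC706, so it did not mark the line labelled female.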

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

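Tests chosen only after the result was seen were scaling and the exchange of media labels for the ERK targets, the exchange of line labels and the minor share of squamous cells for CTO19 among intestinal cells of either kind, and the comparison of the spread of Y-linked genes with that of other genes. The results listed first in this part passed a test of the difference itself, the interaction of line and medium. In them the 2 lines changed differently between EM at 3 days and noEGF at 7 days. That held for 9366 genes and 17 gene lists. The squamous genes of CTO19 in EM and the Y-linked genes within CTO19, given last, did not come from that test.

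The list medians of this difference (CTO19 minus apsMC706) were -1.87 for NF-kB genes, -1.38 for hypoxia, -1.17 for ERK targets, -1 for fetal and YAP genes, -0.856 for glycolysis, -0.758 for ATF4 genes, -0.644 for ribosomal proteins and -0.583 for the unfolded protein response. Smaller medians were -0.351 for the EGF family, -0.178 for FOXO targets and -0.0974 for ribosome biogenesis. Medians above 0 were 0.242 for cholesterol synthesis, 0.26 for oxidative phosphorylation, 0.47 for tight junctions, 0.589 for G2 and M phase, 0.65 for mitochondrially encoded genes and 0.976 for S phase. None of these lists passed camera with an estimated correlation, where 0 of 41 lists had an adjusted p under 0.05 and 4 an unadjusted p under 0.05, while fry called 27.

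The largest gene differences upward were Gsdma (6.787), Hoxb13 (6.775), Nts (5.984), Hoxa11os (5.511), Calm4 (5.505), Tgfb2 (5.338), Rbp2 (5.17) and Krt10 (5.06). Downward they were Wnt7a (-7.15), Il24 (-6.216), Bnc1 (-5.951), Tnc (-5.822), Ngfr (-5.725), Mmp13 (-5.637), Slc16a3 (-5.595) and Oaf (-5.499). Those of Hoxb13, Hoxa11os, Wnt7a, Bnc1 and Oaf have a group at 0 counts and depend on the prior count. The calls of Nts, Hoxa11os, Calm4, Bnc1 and Oaf were lost without some single libraries: Nts without CTO19 EM replicate 1 (adjusted p = 0.0636) or 2 (0.0612), Calm4 without apsMC706 EM replicate 2 (1.809, adjusted p = 0.875), Bnc1 without apsMC706 noEGF replicate 2 (-4.741, adjusted p = 0.233), Oaf without the same library (-1.806, adjusted p = 1) and Hoxa11os without CTO19 noEGF replicate 2 (0.6264, adjusted p = 1). Without apsMC706 EM replicate 1 or 2 the adjusted p was 0.0701 or 0.0672 for Bnc1, 0.0922 or 0.0892 for Oaf and 0.09 or 0.0907 for Hoxa11os. Without CTO19 EM replicate 1 or 2 it was 0.085 or 0.0833 for Bnc1 and 0.125 or 0.128 for Hoxa11os, and without apsMC706 noEGF replicate 1 or 2 it was 0.0585 or 0.0671 for Hoxa11os. Values also moved without apsMC706 noEGF replicate 1 for Calm4 (8.675) and replicate 2 for Tgfb2 (9.032). Of the genes fixed by name, the differences were 0.4136 for Apc, 0.4377 for Smad4, -1.006 for Egfr, 0.6356 for Erbb2, -2.674 for Areg, 0.9782 for Mki67, -0.6581 for Dclk1 and 1.942 for Ddx3y. The Y-linked Ddx3y had 2 to 12 counts in each apsMC706 library, so its difference rests on few counts and is no response of that line.

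As a list median, ERK target genes rose in apsMC706 (0.704) and fell in CTO19 (-0.386) when EGF was left out. Members went both ways in each line, and neither within-line call was kept with an estimated correlation. Against scaling as the cause, the median difference nearer to 0 with other factors was -1.241. Against GC content and gene length, it was -1.14 after a fit on them (SE 0.12, against -1.17 with SE 0.136 before). Media labels exchanged in 1 line do not go with 66 of 68 cell cycle genes that fell in both lines, with 0 in opposite directions. No biological explanation was tested. Medium went with days in culture and line with sex, so a slower change over days and other differences between the lines stay open.

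CTO19 held squamous keratins at high and intestinal genes at low levels. Exchanged line labels do not go with the Y-linked sums, 2480 counts or more in each CTO19 library and 17 or fewer in each apsMC706 library. Of basal squamous genes outside the keratin family 94.1% (16 of 17) were higher, so the pattern was not of keratins alone. The list of these genes was written after the data were seen, so its share is no independent evidence against reads shared between keratins. A minor share of squamous cells among intestinal cells like those of apsMC706 does not go with the intestinal identity genes, whose median log2 difference was -3.15 (bootstrap SE 1.08), 11.3% of the apsMC706 level. That list was written after the data were seen. A minor share among intestinal cells of another kind cannot be told apart from other explanations: over 109 genes of the intestinal cell type lists the median log2 difference was -0.398 (bootstrap SE 0.299), with 43 genes over 2-fold lower and 33 over 2-fold higher. No biological explanation was tested, and neither was a culture of other cells than labelled.

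Y-linked genes were higher in CTO19 in noEGF. Scaling does not go with a lowest median of 1.126 under other factors. A change in the share of cells that carry the Y chromosome cannot be told apart from other explanations. The Y-linked log2 fold changes of 0.894 to 1.39 differed by more than their SE (a chi-square value of 19.5 from the edgeR SE, with an upper tail of 0.00021). Their SD of 0.222 was under the 0.477 (from the median absolute deviation) of genes at large in CTO19, so gene-specific changes on top of a shared rise stay open. A subset of cells with other autosome numbers that gained share could be a part of it and stays open, since the median of chromosome 17 lay 0.203 from that of all autosomes in CTO19, against at most 0.0824 for any autosome in apsMC706. No biological explanation was tested.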

How the results depend on the processing

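Chosen only after the result was seen were the tests of lists within each line, upper-quartile factors for lists, and the replicate block for shared genes. Of 4102 values of named genes under 13 processing alternatives, 3771 (91.9%) kept direction and side of the threshold, 330 were weaker, 1 was stronger and 0 reversed. With 1 library left out, 2879 of 3008 were the same and 128 weaker. Of 262 list medians 207 were the same and 55 weaker, and of 392 with 1 library left out 373 and 19. Against a fold of 1.5 the gene counts were 2221 over both lines, 4331 in apsMC706, 3641 in CTO19, 3194 for the difference of the responses, 5537 between the lines in EM and 7293 in noEGF, which follows from the stricter test. Over both lines the count was 5096 with the replicate block and 1806 with no line term. With libraries summed, where 4 sums are left, it was 84 (83 higher, 1 lower). The cause of the other changes was not tested. With an estimated correlation 0, 0 and 0 lists passed over both lines, in the difference and between the lines in EM, and with fry 30, 27 and 35. With 1 library left out the counts were 6929 to 7409 over both lines, 10013 to 11579 in apsMC706, 10479 to 11191 in CTO19, 8288 to 9231 for the difference, 10827 to 12277 and 12589 to 13828 between the lines in EM and noEGF, and 5301 to 5880 for shared genes, with the lone library assumed to vary like the others. The lists then numbered 19 to 24, 13 to 19 and 14 to 16. Depth limits genes under 3 counts per library.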

Other observations

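All added gene lists in this part were written after the data were seen, and none passed camera with an estimated correlation. The comparison of the Hox medians by their spread and the limit on the splits to 2 libraries of each line in each part were also chosen after the result was seen. Genes of the cornified envelope, the cross-linked outer layer of skin, were called higher without EGF mainly in CTO19. In the comparison over both lines 30 of 34 were higher and 0 lower (median log2 fold change 3.85, adjusted p = 1.76e-13, adjusted p = 0.309 with an estimated correlation). In CTO19 33 rose (median 4.23, adjusted p = 1.38e-13, adjusted p = 0.273 with an estimated correlation), with Flg, which bundles keratin, going from 15.5 to 395 CPM. In apsMC706 5 rose and 29 were not called (median 0.596, or 0 with genes at the floor, adjusted p = 0.344, adjusted p = 0.723 with an estimated correlation). The difference of the responses passed as a list (median 3.08, or 3.89 with genes at the floor, adjusted p = 0.00831, adjusted p = 0.662 with an estimated correlation). Of its members 6 had a higher and 3 a lower response in CTO19. Basal squamous genes moved down in CTO19, 12 lower and 6 higher of 20 (median -0.69, adjusted p = 0.0245, adjusted p = 0.394 with an estimated correlation), and intestinal identity genes up, 10 higher and 1 lower of 16 (median 0.96, adjusted p = 0.0245, adjusted p = 0.394 with an estimated correlation). Between the lines in EM 19 of 20 basal squamous genes were higher in CTO19 (median 5.27, adjusted p = 1.01e-09, adjusted p = 0.193 with an estimated correlation) and 15 of 16 intestinal identity genes lower (adjusted p = 3.68e-06, adjusted p = 0.193 with an estimated correlation).

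Genes of the cleavage-stage embryo, such as the Zscan4 family, fell without EGF, 17 of 17 over both lines (median -2.20, adjusted p = 8.59e-07, adjusted p = 0.328 with an estimated correlation). Their median was -3.57 in apsMC706 (-3.54 with genes at the floor, adjusted p = 0.000113, adjusted p = 0.691 with an estimated correlation) and -1.57 in CTO19 (adjusted p = 5.98e-07, adjusted p = 0.305 with an estimated correlation), and all 17 were higher in CTO19 than in apsMC706 in EM (median 2.28). Reads of these genes cannot be assigned with certainty. Imprinted growth genes such as H19 had 6 higher and 1 lower of 8 over both lines (adjusted p = 0.0586) and 5 and 1 in CTO19 (median 1.33, adjusted p = 0.0317, adjusted p = 0.273 with an estimated correlation).

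Other splits of the 8 libraries into 4 and 4 with the line term were run for the comparison over both lines. Of 34 such splits, the count written before, 1 gave as many genes and 19 as many lists. But 16 of them put 3 libraries of a line against 1, and the lines differed in 71.3% of genes in EM, so only the 18 splits with 2 libraries of each line in each part were used. These are too few for a share under 0.05. Of the 18 splits 1, the real grouping, gave 8157 genes, and the highest other, with the media exchanged in 1 line, gave 1474. For the 17 lists 10 of the 18 splits gave as many, with 24 as the highest other. Of those 10, 1 was the real grouping, 1 had the media exchanged in 1 line, and 8 kept the media fully apart in 1 line, so they still held a medium contrast. The 8 splits with the media balanced in both lines gave 2 to 6 lists and 0 genes.

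Posterior Hox genes were low in CTO19. Of 6 genes of paralog groups 9 to 13, 5 were lower and 1, Hoxb9, higher in EM (median -9.92, adjusted p = 0.0163, adjusted p = 0.375 with an estimated correlation). A difference of all Hox genes, and not of posterior groups alone, was looked for in the anterior groups 1 to 5, which were not lower as a set. Their median was 0.848 (bootstrap SE 0.973, against 2.33 for the posterior groups), with 5 of 10 higher, 3 lower and the lowest at -4.22. The anterior list did not pass (adjusted p = 0.529, adjusted p = 0.657 with an estimated correlation), so the test written before, both lists past the threshold with opposite signs, was not met. The 2 medians lay apart by their spread, but that rule was chosen after the result and treats the genes as independent. That rule therefore cannot decide, for the groups as sets, between a difference of all Hox genes and one of the posterior groups alone. Gene by gene, Hox genes were not all lower, since 5 anterior genes and Hoxb9 were higher. The lower genes were not all posterior either, since 3 anterior genes were lower. No cause of the low posterior genes was tested.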
